A study of Homo sapiens with 16 samples.

How the data were processed

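The series holds 16 sequencing libraries from H9 cells, an established human embryonic stem cell line. Per the labels' protocols, cells were synchronised for 16 h with nocodazole at 100 ng/ml, a drug that arrests cells in mitosis, released, and differentiated for 24 h into mesendoderm, the precursor of endoderm and mesoderm, with activin A at 100 ng/ml and BMP at 10 ng/ml. RNA immunoprecipitation, in general a pull-down of RNA with an antibody before sequencing, gave 8 libraries that the labels call 7mG, a name for 7-methylguanosine. The other 8 libraries are inputs, sequenced without the pull-down. Each kind of library comes from 4 conditions with 2 biological replicates each: untreated cells, cells with the CDK1 inhibitor RO3306, cells carrying an inducible shRNA against CDK1 without tetracycline, and such cells with tetracycline, which induces the knockdown. The labels' protocol text also speaks of ChIP-seq, hydroxyurea and a DNA library kit, and it does not describe the antibody or the fragmentation of the RNA.

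The submitters' processing notes name the GRCh38 build, HISAT2 and deepTools, without versions or settings. The authors deposited 1 list of peaks per condition, whose name gives MACS2 as the caller and describes the peaks as common to both replicates. The coordinates of these peaks in bases are the only values in the authors' deposited lists, which hold no score, no strand and no value per library. The authors also deposited 2 lists of differential peaks made with exomePeak by name, 1 for the inhibitor and 1 for the knockdown, with exon blocks, a gene identifier, a strand and a score. The score is read as a p-value in the authors' deposited table, because it lies between 0 and 1 and falls as low as 3.3e-189, but per the file headers the test behind it, any correction and the direction of the difference are not stated. Gene models came from the deposited Ensembl annotation, which per the file headers is for GRCh38.

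No file gives reads or counts per library, so the depth of every sample is unknown, the spread between replicates could not be computed, and no p-value was computed across genes. Intervals of a share are exact Clopper-Pearson binomial intervals at 95% and cover counting error only. Intervals of a difference between shares are symmetric about the difference and are not of this exact kind. The interval of the ratio of covered exonic bases, with over without tetracycline, comes from resampling chromosomes. None of these intervals covers the spread between replicates.

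Peaks were compared with interval code written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The interval code was checked against bedtools 2.31.1 in 20 comparisons, of which 0 differed. An overlap of 1 base counted as shared. A gene had a peak when a peak covered at least 1 base of an exon of any of its transcripts, and genes were protein-coding unless stated. Because the consensus peaks carry no strand, a peak over genes on both strands counted for each of them. Each peak was placed in the first feature it touched, in the order 5' UTR, 3' UTR, coding sequence, other exon, intron, using the transcript with the longest coding sequence of each gene. Consensus peaks were placed by their whole span and differential peaks by their exon blocks, with the midpoint taken along the span or the exonic length.

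The comparisons were: untreated against RO3306, without against with tetracycline, and the untreated list against the list without tetracycline. The last shows how far lists differ without an intended perturbation of CDK1, though these cells also differ in whether they carry the shRNA. The number of genes with a peak in both control lists and in neither perturbed list was set against 10000 random draws. The overlap of the differential genes was compared with random draws from 6706 genes with an exonic peak in any consensus or differential list, which was also the pool for list members with a differential peak. Members of 18 gene lists were counted, and each count was placed among 10000 random lists of the same size matched by 5 classes of exonic length. A count was called apart from chance when at most 2.5% of random lists were as high or as low. On simulated lists of 40 genes without any effect, 3% fell in these outer tails with matching and 12% without it. With a strong effect, where hits were drawn at 4 times the weight, 99% did. Most gene lists here had fewer members with a peak, so this says little about their power to show a weaker effect. Where genes had a peak in both lists of a comparison, the ratio of their covered exonic bases was compared in the same way, which was not simulated.

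The comparisons, the gene lists, the main random draws and the rule for named genes were set before the data were examined. The ratio of covered exonic bases per gene list, its minimum of 6 members, its matchings and the same ratio between the control lists were added after the list medians had been seen. Genes named by rule were, for each perturbation, CDK1, METTL1 and WDR4, the 20 protein-coding genes with the strongest score, the first 3 members of each gene list with a peak in exactly 1 of the lists compared or with a differential peak, and up to 10 genes with the strongest scores under both perturbations. Other genes, such as NUMA1, CKAP5, CENPF, TRIM28, TBX6 and CDX2, were chosen after their values were seen.

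Alternatives covered the overlap that counts as shared, lists of equal length, fixed windows of 1000 bases, gene bodies, all gene types, the stricter part of the differential lists, all transcripts, peak midpoints and the backgrounds of the random draws. The inputs were not used, since no file holds values for them. The undifferentiated cells named in the series description were not analysed, since no file holds them. Levels of the gene or the protein, and hence the efficiency of the knockdown, are not among the deposited values.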

Results

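RNA immunoprecipitation libraries that the labels call 7mG, from H9 cells after 24 h of mesendoderm differentiation, were compared across 4 conditions of 2 biological replicates each. The conditions were untreated cells, cells with RO3306, an inhibitor of the mitotic kinase CDK1, and cells carrying an inducible shRNA against CDK1 without or with tetracycline. The values come from 1 consensus peak list per condition and 2 lists of differential peaks, so no value carries a spread between replicates, and the depth is unknown. The series title names the question, the effect of the cell cycle regulator CDK1 on differentiation.

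The untreated list held 13342 peaks over 4791 protein-coding genes, and the RO3306 list held 8484 peaks over 4524. The list without tetracycline held 25664 peaks over 5100 genes, and the list with tetracycline held 12615 over 5054. Of all protein-coding genes, 3218 had a peak in all 4 lists and 6666 in any. The peaks covered 15.04 Mb in the untreated list, 10.2 Mb with RO3306, 8.25 Mb without tetracycline and 13.6 Mb with tetracycline. Peaks were narrow without tetracycline, with a median width of 226 bases and a minimum of 115, whereas the medians of the other lists were 802 bases (untreated), 915 (RO3306) and 785 (with tetracycline), with minimums of 463, 535 and 595. METTL1 (ENSG00000037897), the catalytic subunit of an enzyme that methylates guanosine at position 7 in RNA, had peaks in all 4 lists, over 1508, 1015, 1326 and 1575 exonic bases (untreated, RO3306, without and with tetracycline). CDK1 itself and WDR4, the partner of METTL1, had a peak in none of the 4 lists and no differential peak.

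**Figure D1:**
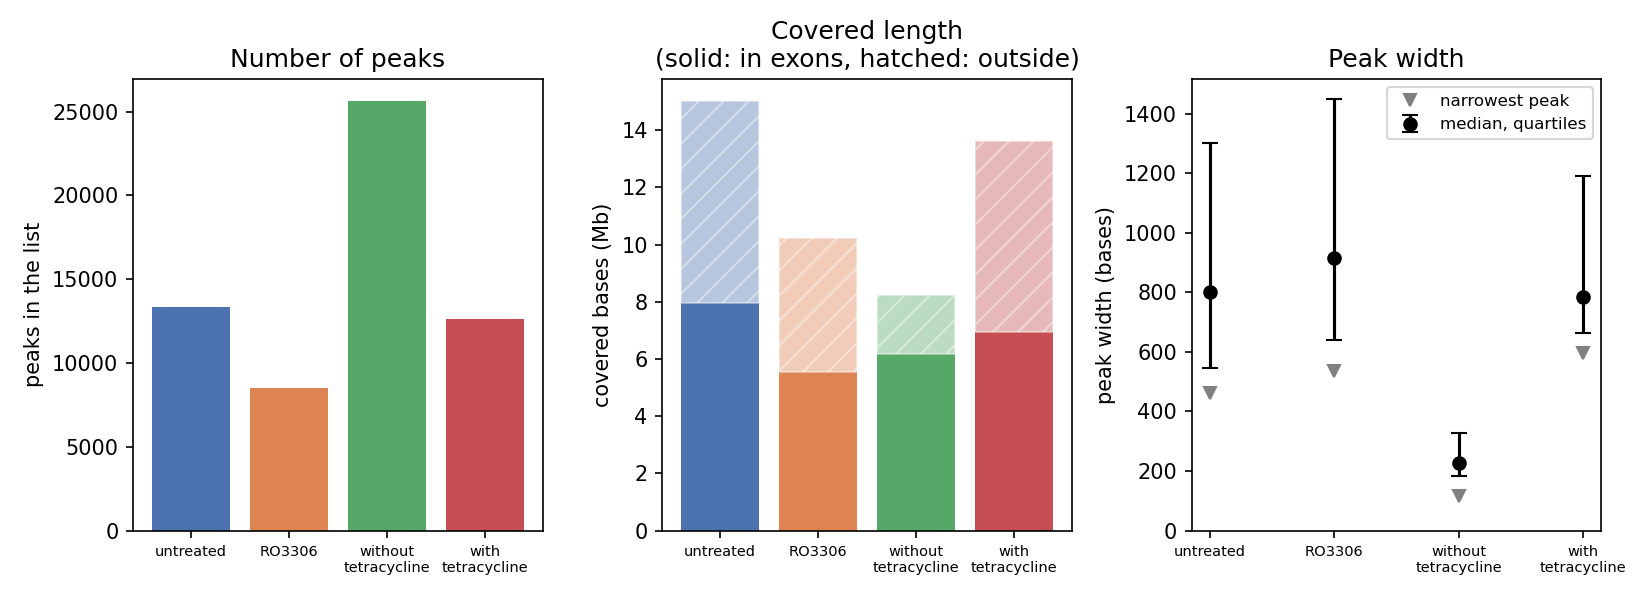
Number of peaks (left), covered length in Mb split into exons and the rest (middle) and peak width in bases (right) for the 4 consensus lists. The list without tetracycline held the most peaks (25664) and covered the least sequence (8.25 Mb), with a median width of 226 bases.

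The inhibitor comparison asked how the peaks differed when CDK1 activity was blocked. With RO3306, 3 of the 15 abundant cytoskeletal and housekeeping genes with an untreated peak had none (59.93% of random lists held as many): ACTB, a cytoplasmic actin, was covered over 2220 exonic bases in the untreated list and 0 in the RO3306 list, ACTG1 over 2424 and 0, and the glycolytic enzyme GAPDH over 1695 and 0. The pluripotency factor POU5F1 went from 885 covered bases to 0, and the mesendoderm factor MESP1 from 712 to 0. TBXT (ENSG00000164458, named T in the annotation), which marks the primitive streak, kept a peak but over 621 bases in place of 2512. In the other direction, the mesoderm genes BMP4, NKX2-5 and SNAI1 had a peak with RO3306 and not in the untreated list, over 629, 889 and 653 bases, while the control list without tetracycline covered BMP4 over 653 and SNAI1 over 1470 bases. Of the genes with a peak in either list, 3830 had one in both, 961 in the untreated list only (20.1% of its genes, 95% interval 18.9 to 21.2) and 694 in the RO3306 list only (15.3%, 14.3 to 16.4). With lists of equal length, 8484 peaks each, the order turned, to 698.5 genes in the untreated list only and 1297 in the RO3306 list only. Only the untreated list was thinned for this, which can only lower the first count and raise the second. The turned order is therefore no sign of more gain than loss.

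Among the gene lists, primitive streak and mesendoderm genes had 12 of 22 members with a peak in the untreated list and 9 with RO3306. MESP1, FGF17 and LEFTY2 accounted for the difference, and no member had a peak with RO3306 only. The 9 members with a peak in both lists, TBXT among them, had a median ratio of covered bases of 0.811, with 8 covered less. That is near the 0.817 of all genes, and 17.46% of random lists were as low. The mesoderm list went from 0 of 17 members to 5, BMP4, NKX2-5, SNAI1, MSX1 and MSX2, and 7.68% of matched random lists held as many genes with a peak in the RO3306 list only. Pluripotency genes numbered 7 and 6 of 19, and SOX2 and KLF4 had a peak in the RO3306 list only. The G2/M and mitosis list held 21 and 18 of 40 members with a peak. CDC25C, WEE1, TOP2A and CENPA had theirs in the untreated list only, over 86, 225, 2827 and 576 bases. In the knockdown CDC25C and WEE1 kept a peak, over 859 and 254 bases with tetracycline. WEE1 encodes the kinase that restrains CDK1 and CDC25C the phosphatase that activates it. G1/S and replication genes numbered 17 and 16 of 34, and E2F1 was covered over 268 bases in the untreated list and 0 with RO3306. Replication-dependent histone genes, whose close sequence likeness lets reads be shared, numbered 5 and 13 of 71, of which 10 had a peak in the RO3306 list only, but 16.75% of matched random lists held as many. The only untreated-only or RO3306-only count in the outer tails was that of the translation initiation and elongation factors, of which 2 of 34, EIF2A and EIF4A3, had a peak in the untreated list only. Of random lists, 1.56% were as low, and 7.78% when matched on covered bases.

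Of the untreated peaks, 51.8% (51.0 to 52.7) overlapped a RO3306 peak, and 80.4% (79.6 to 81.3) of the RO3306 peaks overlapped an untreated one. In genes with a peak in both lists, coverage was lower with RO3306 in 2829 of 3830, with a median ratio of 0.817. Among the largest named differences, SF3B1, a core protein of the U2 snRNP, was covered over 5428 bases without and 611 with RO3306, GLUL, which makes glutamine, over 7149 and 1371, and the translation factor EIF4G2 over 7871 and 1447. PABPC1, the poly(A)-binding protein, went the other way, from 986 to 2480 bases. The median ratio of the G2/M and mitosis genes was 0.574, with 16 of 17 covered less, and 0.81% of random lists were as low. G1/S and replication genes had a similar median of 0.588, with 9 of 13 covered less, just outside the outer tails (2.79% as low). DNA methylation and chromatin regulators had a median of 0.416, with 14 of 16 covered less and 0.44% of random lists as low. DNMT1, the maintenance DNA methyltransferase, went from 2351 to 597 bases and PKMYT1, an inhibitory kinase of CDK1, from 2612 to 457. The G2/M result left the outer tails, at 3.05%, when random lists were matched on the coverage in the untreated list alone. It stayed in them, at 1.63%, when they were matched on exonic length and that coverage together. Ribosomal protein genes lay in the opposite tail, with a median of 0.939 and 2.49% of random lists as high.

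The authors' deposited table of differential peaks for the inhibitor held 2096 peaks over 1334 protein-coding genes, and it gives no direction. HNRNPH1 (ENSG00000169045), a splicing regulator, ranked first, with a peak at chromosome 5, 179614178 to 179623664, in GRCh38 that touches the 5' UTR and a score of 3.3e-189 in the authors' deposited table. PABPC1 (chromosome 8, 100686264 to 100722600) had the same score in the authors' deposited table, and the chaperone HSP90AA1 (chromosome 14, 102080738 to 102087102) followed at 8e-149. The splicing and RNA-processing factors DDX5, SRSF7, SUGP2, SF3B1 and SRSF1 were also among the 20 strongest, together with EIF4G2, RPL3, NCL and ACTG1. The genes of HNRNPH1, PABPC1, HSP90AA1 and all others among the 20 lie on the minus strand, as do 95.1% of all genes in the authors' deposited table. Ribosomal protein genes held a differential peak in 31 of 77 members with a peak in any consensus or differential list, and 0% of 10000 matched random lists held as many. Abundant cytoskeletal and housekeeping genes held one in 9 of 17 (0.2% as high) and histone genes in 0 of 20 (0.85% as low, 11.72% on minus-strand genes matched on covered bases). TBXT had a score of 4.6e-07 in the authors' deposited table, and POU5F1 one of 0.0027. Above 0.05 lie 651 of the scores (31.1%) in the authors' deposited table.

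The knockdown comparison asked the same question with an shRNA in place of a drug. No cells without this shRNA received tetracycline, so an effect of tetracycline itself cannot be told apart from that of the knockdown. BUB1B, a spindle checkpoint kinase, was covered over 2273 exonic bases without tetracycline, 0 with it and 864 in the untreated list, and BUB1 over 2649, 1086 and 0. Of the 33 G2/M and mitosis genes with a peak without tetracycline, 8 had none with it, a number that 18.58% of random lists reached. The regulators DNMT3A, which methylates DNA, and SUZ12, a Polycomb subunit, went from 521 and 128 bases to 0. The primitive streak genes kept their peaks, with 15 of 22 members without and 17 with tetracycline, and TBXT was covered over 2517 and 2123 bases. MSX1 and MSX2, transcription factors downstream of BMP signalling, had a peak with and not without tetracycline, over 910 and 247 bases. Of all genes, 4258 had a peak in both lists, 842 without tetracycline only (16.5%, 15.5 to 17.6) and 796 with tetracycline only (15.7%, 14.8 to 16.8). With lists of equal length these were 807 and 1460 genes. The list without tetracycline was thinned more for this, so that order is no sign of gain either.

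In the G2/M and mitosis list, 33 of 40 members had a peak without and 26 with tetracycline, against 21 in the untreated list. The genes without tetracycline only were BUB1B, MKI67, KIF11, CENPE, CENPF, DLGAP5, ANLN and INCENP, of which BUB1B alone also had a peak in the untreated list. CDC25B alone had a peak with and not without tetracycline, and it was covered in the untreated list too. N6-methyladenosine machinery genes numbered 7 and 4 of 18, with WTAP among those without tetracycline only (150 bases), and chromatin regulators 28 and 21 of 40, neither apart from random lists (11.03% and 49.8% as high). G1/S and replication genes numbered 21 and 17 of 34, and p53 and stress response genes 14 and 16 of 24, where BBC3, a pro-apoptotic p53 target, had a peak with tetracycline only (843 bases). Histone genes numbered 7 and 15 of 71, with 43.69% of random lists holding as many with tetracycline only, and 6 of them, among them HIST1H2AM and HIST1H4C, also had a peak with RO3306 and in neither control list. Pluripotency genes stood at 7 of 19 in both lists. Cytosolic ribosomal protein genes had the only count in the outer tails, since 2 of 69, RPL22L1 and RPS4X, had a peak without tetracycline only and 0.26% of random lists were as low.

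Of the peaks without tetracycline, 56.3% (55.7 to 56.9) overlapped a peak with it, and 81.3% (80.6 to 82.0) of the peaks with tetracycline overlapped one without. The first share was 4.78% when both peaks had to overlap over at least 50% of their length. Covered exonic bases in genes with a peak in both lists were higher with tetracycline in 2718 of 4258, with a median ratio of 1.15. G2/M and mitosis genes went against this, with a median of 0.650, 19 of 25 covered less and 0% of random lists as low. NUMA1, a spindle pole protein, was covered over 4964 bases without and 1010 with tetracycline, and CKAP5, which promotes microtubule growth, over 5222 and 1388, but the untreated list covered them over 1244 and 0 bases. Pluripotency genes had a median of 0.597 (5 of 6 covered less, 0.33% as low), and ribosomal protein genes one of 1.46 (55 of 67 covered more, 0.07% as high). Chromatin regulators had a median of 0.790, and 6.59% of random lists were as low. Between the control lists, untreated over without tetracycline, the same medians were 0.920 for G2/M genes (4.15% as low), 0.590 for pluripotency genes (1.96% as low), 0.888 for chromatin regulators (3.68% as low), 1.29 for ribosomal protein genes (4.37% as high), and 0.832 for G1/S and replication genes (1.97% as low). Pluripotency and G1/S genes were thus in the outer tails without an intended perturbation of CDK1, the former by nearly the same ratio as in the knockdown. The other 3 lists were not, though ribosomal protein genes reached 2.5% when random lists were matched on length and coverage together. However, the G2/M median between the controls covers only 19 of the 33 genes with a peak without tetracycline. It leaves out genes with no untreated peak, such as MKI67 (3716 bases without tetracycline), BUB1 (2649) and CKAP5 (5222). The knockdown median likewise leaves out the 8 genes with no peak with tetracycline. Lower G2/M coverage is therefore not shown to be particular to the knockdown. The knockdown and control ratios share the list without tetracycline as denominator.

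**Figure D2:**
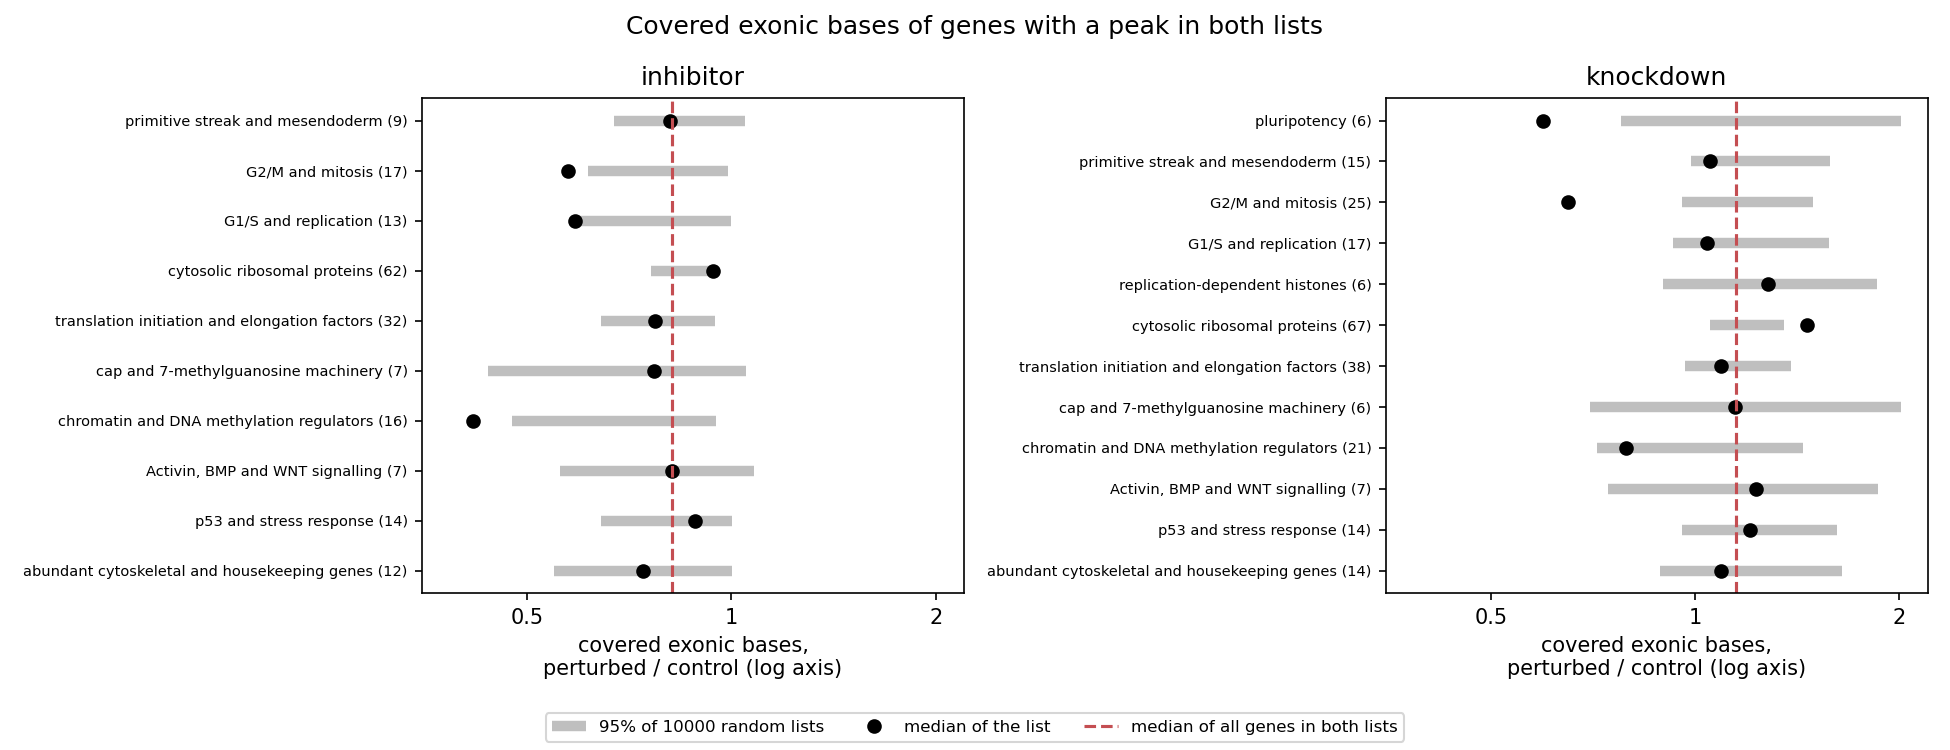
Covered exonic bases in the perturbed list over those in the control list (log axis) for genes with a peak in both, as the median per gene list (points), with the range of 95% of 10000 random lists (grey bars) and the median of all genes (dashed line), member counts in parentheses. G2/M and mitosis genes sit at 0.574 for the inhibitor and 0.650 for the knockdown, to the left of both grey bars.

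The authors' deposited table for the knockdown held 2160 differential peaks over 1392 protein-coding genes. HNRNPH1 again ranked first, over the same interval, with a score of 1.1e-182 in the authors' deposited table. NCL, the nucleolar protein nucleolin, ranked second (chromosome 2, 231454761 to 231464014), and the splicing factor SRSF1 (chromosome 17, 58004910 to 58007346) came next, at 3.7e-153 and 4e-74 in the authors' deposited table. RPL8, UBR4, RPS23 and IVNS1ABP followed. The peak over ATG10, at rank 9, lies on the plus strand where the 3' end of ATG10 overlaps RPS23 on the minus strand. Ribosomal protein genes held a differential peak in 26 of 77 members (0.82% of random lists as high), housekeeping genes in 9 of 17 (0.27%) and histone genes in 0 of 20 (0.56% as low, 7.52% on minus-strand genes matched on covered bases). TBXT had a score of 8.6e-21, ACTB one of 3.5e-16 and EZH2, the catalytic subunit of Polycomb complex PRC2, one of 1.2e-17 in the authors' deposited table. Scores above 0.05 number 721 (33.4%) in the authors' deposited table.

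The same genes carried differential peaks under the drug and the shRNA more often than in random draws. HNRNPH1, DDX5, NCL, SRSF1, SUGP2, SF3B1, RNF44, SRSF7, EIF4G2 and GLUL had the strongest scores under both, and 846 genes were shared, 63.4% of the inhibitor genes and 60.8% of the knockdown genes. Random draws gave a median of 277 and at most 333. Since nearly all of these genes lie on the minus strand, the draws were repeated there, and 825 shared genes were found where random sets gave 502, or 691 when matched on covered bases (at most 731). The count fell from 3.05 times the random mean to 1.64 and 1.19 times in these 2 settings. Transcript abundance is not among the deposited values and could not be matched, so the remaining excess does not by itself show a shared response to CDK1. Of the inhibitor peaks, 49.8% (47.6 to 51.9) overlapped a knockdown peak. The ribosomal protein genes held 22 members with a differential peak under both, the housekeeping genes 8 and the translation factors 7.

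**Figure D3:**
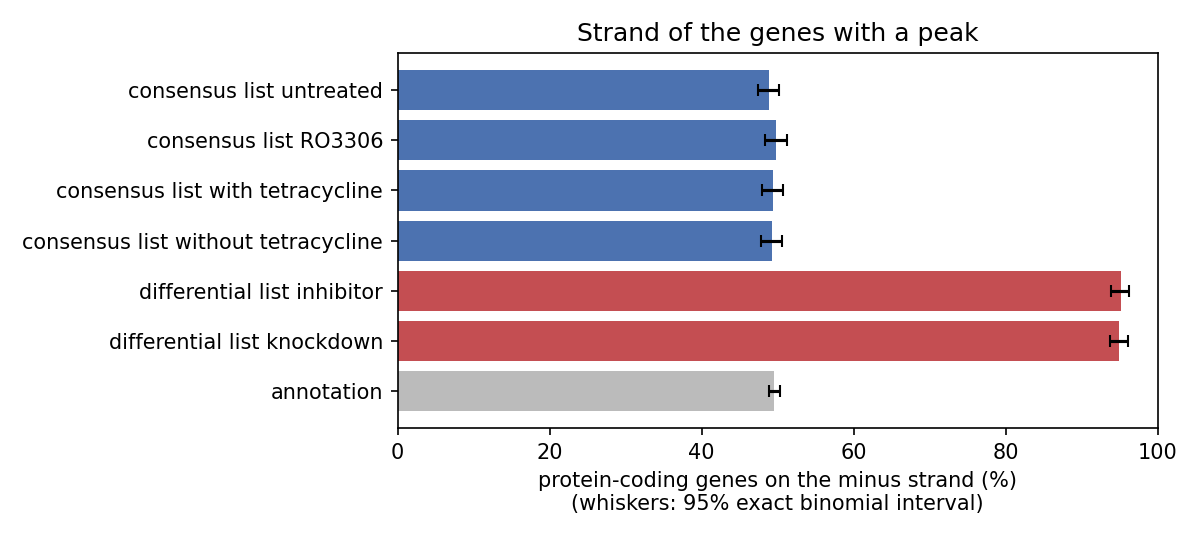
Percent of protein-coding genes on the minus strand among genes with a peak in each consensus list, in each differential list and in the annotation, with 95% exact binomial intervals (whiskers). The consensus lists lie between 48.8% and 49.8% and the differential lists at 95.13% and 94.97%.

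Genes with a peak in both control lists and in neither perturbed list numbered 151 among the 3895 genes with a peak in both control lists. The chromatin regulators SUZ12 and TRIM28 were among them, SUZ12 with 325 and 128 covered bases in the control lists. Random draws gave a median of 40 and at most 62, or a median of 45 (at most 72) when matched on exonic length and of 73 (at most 103) when matched on covered bases. With lists of equal length the number was 91.5, at 2.43 times the random mean. The genes with a peak in both perturbed lists and neither control list numbered 129, and MSX1, MSX2 and 6 histone genes were among them.

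The control lists, both without an intended perturbation of CDK1, differed over single marker genes. The primitive streak genes GSC, TBX6 and CDX2 had a peak without tetracycline, over 923, 2272 and 1475 bases, and none in the untreated list, and the other 12 streak genes with a peak without tetracycline had one in both, with a median ratio of covered bases, untreated over without tetracycline, of 1.05 (36.92% of random lists as low). The mitotic genes BUB1 and MKI67 were covered over 2649 and 3716 bases without tetracycline and 0 in the untreated list. GAPDH was covered over 1695 bases in the untreated list and 0 without tetracycline. Of the untreated peaks, 71.4% (70.7 to 72.2) overlapped a peak without tetracycline, and 55.61% (55.001 to 56.22) the other way round. With lists of equal length the first share was 29.96%, and by covered bases 34.7%. Of the bases covered by either control list, 28.8% were covered by both. The same share was 46.0% for the untreated list and the list with tetracycline, and 45.4% for the untreated and RO3306 lists. For genes with a peak these shares were 65.0%, 67.8% and 69.8%. By these shares of bases and genes, the untreated list was thus nearer to each perturbed list than to the other control list. The share of untreated peaks that overlapped, with lists as deposited, gave the opposite order. It was 71.4% for the list without tetracycline, 63.1% for the list with tetracycline and 51.8% for the RO3306 list. The ranking therefore depends on the measure. At the gene level 3895 genes had a peak in both, 896 in the untreated list only and 1205 without tetracycline only. The order turned to 1461 and 1078.5 with lists of equal length, where the list without tetracycline was again thinned more. The markers of other cell types were few in every list, with 1, 1, 2 and 3 of 15 neuroectoderm genes and 2 of 12 trophoblast and amnion genes in each of the 4 lists. Definitive endoderm genes (0, 0, 1 and 1 of 12) and mesoderm genes (0, 5, 3 and 5 of 17) were also few, unlike primitive streak genes. Few peaks alone therefore do not mark a cell type as absent. Mitochondrially encoded genes had 0 of 13 throughout, which may reflect naming only. Their exons were searched under the chromosome name chrMT, and whether the peak lists use that name was not checked.

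**Figure D4:**
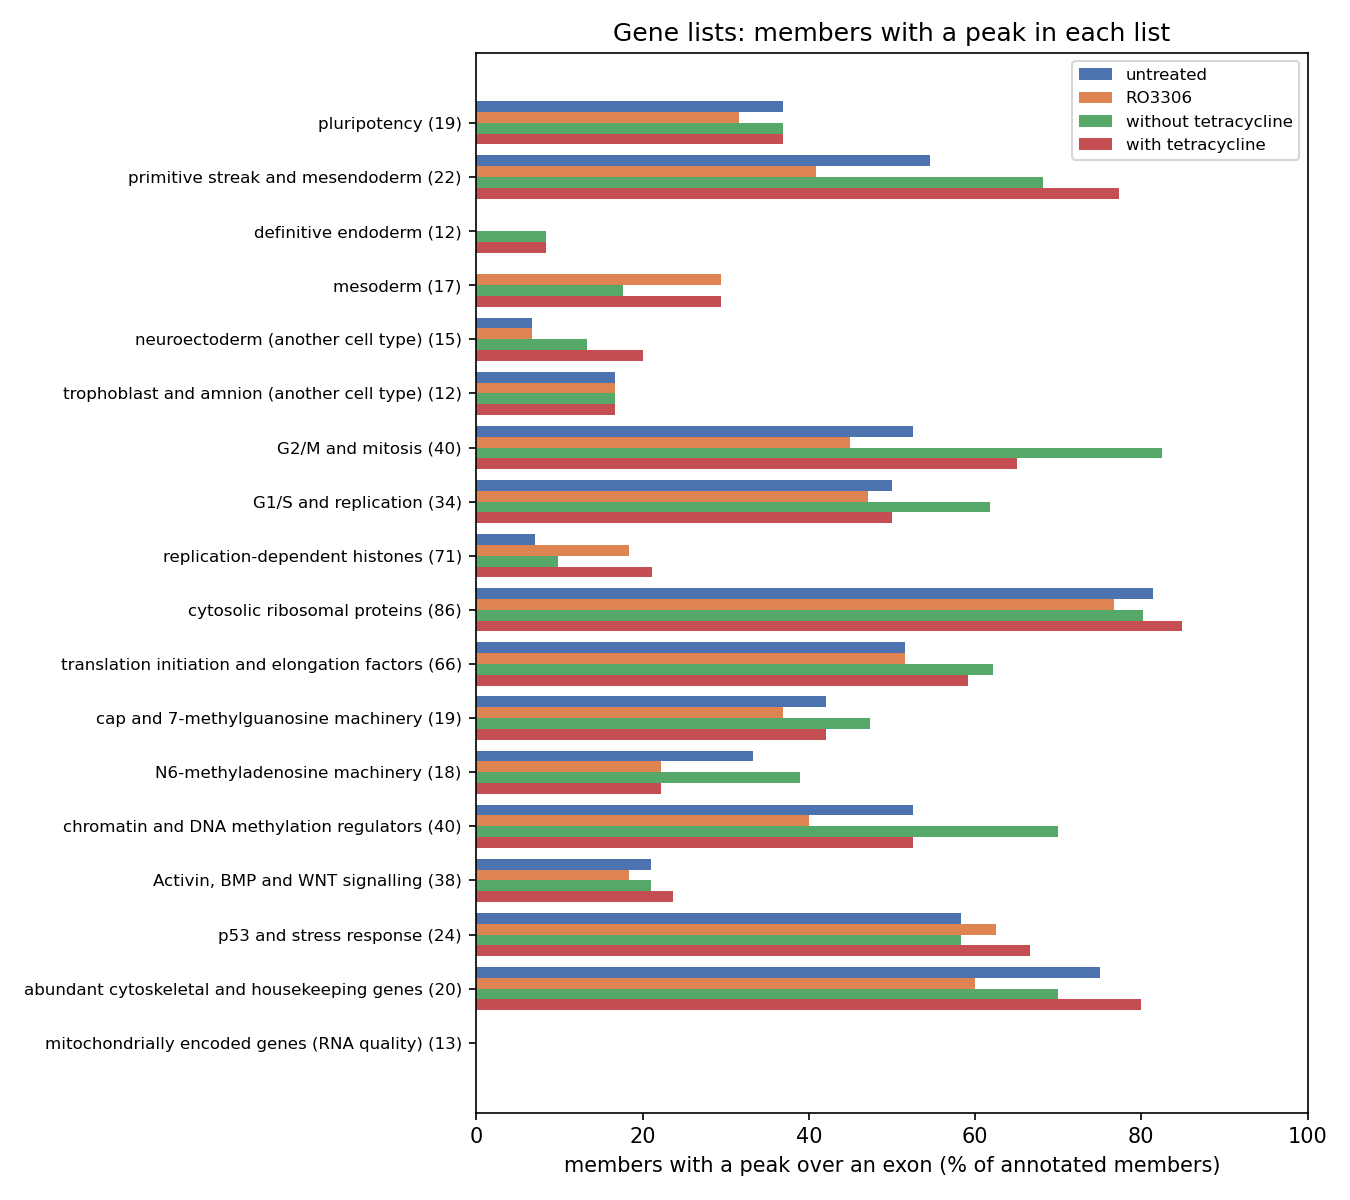
Percent of annotated members with a peak over an exon (x axis) for the 18 gene lists (y axis, member numbers in parentheses) in the 4 consensus lists. The G2/M and mitosis list has 21, 18, 33 and 26 of 40 members with a peak in the untreated, RO3306, without and with tetracycline lists.

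Along the transcripts, coding sequence was the most frequent feature of each consensus list when a peak was placed by any overlap. The coding share was 53.3% in the untreated list (52.5 to 54.2), 45.4% with RO3306 (44.4 to 46.5), 67.1% without tetracycline (66.6 to 67.7) and 51.8% with it (51.0 to 52.7). The share over a 3' UTR but no 5' UTR was 22.0% untreated and 31.4% with RO3306, and 15.5% without and 24.7% with tetracycline. The 5' UTR share was 11.2%, 10.8%, 6.14% and 13.6% in the same order. Differential peaks touched the 5' UTR in 23.4% (inhibitor) and 25.5% (knockdown) of cases, as those of HNRNPH1, SRSF1, SF3B1 and TBXT do, and the 3' UTR but no 5' UTR in 38.0% and 35.2%, as those of GLUL and EIF4G2 do. A wide peak touches more features, and by the midpoint of each peak introns held the largest share of the untreated (52.4%), RO3306 (49.2%) and with-tetracycline (57.3%) lists, with coding shares of 17.2%, 19.1% and 13.8%. By midpoint the 3' UTR difference of RO3306 shrank to 0.543 percentage points (-0.0882 to 1.17) and the 5' UTR difference of the knockdown to 0.0531 (-0.275 to 0.381). The coding difference of RO3306 turned to 1.86, the 3' UTR difference of the knockdown to -5.80, and the 5' UTR excesses of the differential peaks to -0.594 and -0.320. Those excesses set unlike measures side by side, since differential peaks were placed by exon blocks and consensus peaks by whole spans. By midpoint, coding sequence held the largest share of the differential peaks, 46.7% (inhibitor) and 49.9% (knockdown).

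**Figure D5:**
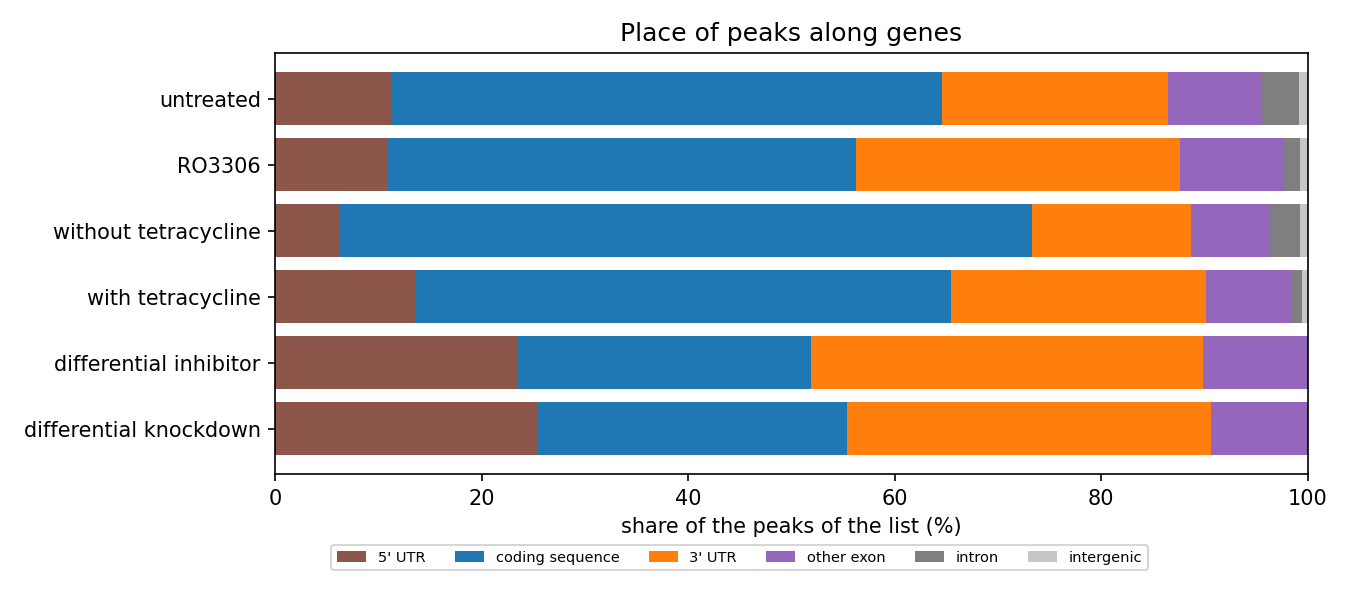
Share of the peaks (%, x axis) in each feature, by any overlap, for the 4 consensus lists (whole spans) and the 2 differential lists (exon blocks only). Coding sequence takes 67.1% of the peaks without tetracycline and 28.5% of the differential peaks of the inhibitor.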

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

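Of the tests in this part, those on joined peaks, on the covered length of the control lists, on the strand makeup of the genes and on sets matched on covered bases or on exonic length were chosen after the result was seen, and the others were written before. The perturbations differed in direction in several measures, which rests on 1 list per condition and was not tested: covered bases stood at 0.680 of the control with RO3306 and at 1.65 with the knockdown. The net change in members with a peak, knockdown minus inhibitor, was 5 for primitive streak and mesendoderm genes, 8 for cytosolic ribosomal protein genes, 2 for Activin, BMP and WNT signalling genes and 5 for abundant cytoskeletal and housekeeping genes. Peaks over exons of other gene types only, which the comparisons of protein-coding genes leave out, numbered 754 in the untreated list, 584 with RO3306, 1099 without tetracycline and 761 with it.

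With tetracycline the list held fewer peaks than without it but covered more sequence. Joining peaks at most 500 bases apart left 1.75 times as many peaks without tetracycline, which argues against single wide peaks that stand for several narrow ones as the whole cause. Wider peaks that reach into introns may account for it, since 85.7% of the extra bases lie outside exons, but the exonic bases were still 1.12 times as many (1.08 to 1.16 by resampling chromosomes). The bound of 1.1 was written before and the value exceeds it, and the resampling was added after that was seen and includes the bound, so this explanation stays open. A widening by the knockdown cannot be told apart from differences between lists, because the untreated list covered 1.82 times as much as the list without tetracycline.

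The differential peaks lie on the minus strand in 93.9% (inhibitor) and 93.5% (knockdown) of cases. The genes with peaks argue against strand makeup as the cause, since at most 49.8% of them are on the minus strand, and so does the lowest share of any chromosome with at least 20 differential peaks, 88%, against a few chromosomes. Plus-strand differential peaks lay over a minus-strand exon 3.69 times as often as plus-strand genes with consensus peaks did (91.3% and 94.3% against 25.2%), as a counting step that kept reads of 1 strand only might give. If so, most plus-strand genes, such as SOX2, EVX1 and CCNB1, could not have been called, and the absence of a gene from the differential lists says little. No biological explanation was tested.

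The 151 genes with a peak in both control lists and in neither perturbed list outnumber those of random sets matched on exonic length (at most 72) or on covered bases (at most 103). These values argue against length or thin coverage, by these measures, as the whole cause. Peak strength, peak width and transcript abundance were not matched, so weak or narrow peaks in the control lists remain possible. A loss through CDK1 by either route may be 1 cause, and splitting the 4 lists by perturbation left 280 genes confined to 1 pair of lists. The split by cell line, with or without the shRNA, left 621, and the crossed split 186. By single pair, the control pair held the 151 genes, the pairs of the split by line 211 and 410. In the crossed split, whose pairs share neither line nor perturbation, 1 pair held 125 genes and the other 61. The bound written before, that no other split gives as many, was therefore missed, and the first verdict went against the perturbation. That bound was judged wrong afterwards from the design, since line and perturbation are separate factors and a large difference between lines excludes no second one, so with 1 list per condition the perturbation cannot be told apart from other differences between lists.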

How the results depend on the processing

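Of 126 values under alternative settings, 90 kept their direction and side or stayed near the reported value and 36 changed, and of 270 calls of named genes 267 stayed, the exceptions being HIST1H2AE and DDIT3 in fixed windows and ATF3 over gene bodies. The cause was not tested unless given. The number of peaks with over without tetracycline, 0.492, reversed to 1.65 by covered bases and 1.12 by covered exonic bases. Asking for 50% reciprocal overlap moved the shares of overlapping peaks to 44.4% (inhibitor), 4.78% (knockdown) and 11.4% (controls), lists of equal length moved them to 37.9% (knockdown) and 29.96% (controls), and covered bases to 64.0% and 34.7%. With equal lengths, genes in the perturbed list only numbered 1297 (inhibitor) and 1460 (knockdown), above the 698.5 and 807 in the control list only, where the control lists were thinned more, and genes lost under both 91.5. With all gene types, 1369 genes were in the list with tetracycline only, by construction. The stricter part of the differential lists held 1049 and 1093 peaks by construction, 94.9% and 94.7% on the minus strand, and 54.9% of the inhibitor genes were shared. Scores of at most 0.05 left 1439 knockdown peaks and 57.1% shared genes, and counting overlapping peaks gave 49.8%. By midpoint, the differences in location were 0.543 (3' UTR, RO3306), 1.86 (coding, RO3306, reversed), 0.0531 (5' UTR, knockdown), -5.80 (3' UTR, knockdown, reversed), -42.6 (coding, knockdown), -0.594 and -0.320 (5' UTR of differential peaks, both reversed) percentage points. With all transcripts they were 10.8 (3' UTR, RO3306), 8.26 (5' UTR, knockdown), -16.4 (coding, knockdown) and 15.3 (5' UTR, differential peaks of the inhibitor). Among list results, histones (11.72% and 7.52%), translation factors (7.78%) and G2/M coverage with the inhibitor (3.05%) left the outer tails when matched on coverage. G2/M coverage with the inhibitor stayed in them (1.63%) when exonic length was matched as well. Covered bases (for overlaps), equal lengths (for genes in 1 list only), exonic bases, fixed windows, scores of at most 0.05, matching on coverage and the strand backgrounds were chosen after seeing the data. No paired analysis was possible because no file holds values per replicate, and for the same reason no replicate could be left out. The consensus lists hold no score, so a stricter threshold for them could not be run. The depth is unknown.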

Other observations

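The test of snoRNA host genes in this part was written before its result was seen. Non-coding genes carried peaks as well. Peaks that touched exons of other gene types only made up 5.65% of the untreated list (95% interval 5.27 to 6.06), 6.88% with RO3306 (6.35 to 7.44), 4.28% without tetracycline (4.04 to 4.54) and 6.03% with it (5.62 to 6.46). Processed pseudogenes, copies of mRNAs that often share reads with their parent gene, were the most frequent type named, with 249, 294, 386 and 433 genes (untreated, RO3306, without and with tetracycline). Antisense genes numbered 61 and 33 with the inhibitor comparison and 58 and 35 with the knockdown, lower in both perturbed lists, and snoRNA genes 36 and 28, and 36 and 27. Genes for lincRNAs numbered 74 and 64, and 62 and 70. No test was run on these counts.

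Genes with a peak in 1 list only differed in length from one another. Genes with an untreated peak only had a median exonic length of 4868 bases and those with a RO3306 peak only 3740 bases. In the knockdown the medians were 5649 bases without and 3789 bases with tetracycline.

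A hypothesis was that host genes of snoRNAs, many of which encode ribosomal proteins and translation factors, carry differential peaks more often than other genes. Among minus-strand genes outside the ribosomal protein list, 31 of 61 hosts had one for the inhibitor and 30 of 61 for the knockdown, and 12.52% and 24.29% of random lists matched on covered bases held as many. The result was therefore negative. With the ribosomal protein genes included, 42 of 73 hosts had a differential peak for the inhibitor, and 0.7% of random lists held as many, and 37 of 73 for the knockdown, with 19.06%.

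Of 96 counts of list members compared with random lists, 8 lay in the outer tails where 4.8 were expected by chance at most, 6 of them among the counts of differential peaks. Of 22 medians of covered bases 6 did, where 1.1 would be expected. The ratio and its minimum of 6 members were chosen after the medians were seen, so that expected number is no fair measure of chance. The lists of definitive endoderm, with 0, 0, 1 and 1 of 12 members with a peak, of the cap and 7-methylguanosine machinery, with 8, 7, 9 and 8 of 19, and of Activin, BMP and WNT signalling, with 8, 7, 8 and 9 of 38, were in no outer tail. Gene identifiers in the differential lists carried the same version as the deposited annotation in 11.5% (inhibitor) and 12.7% (knockdown) of peaks, and 5 and 4 peaks had no match in it.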
